A study of Mus musculus with 6 samples.

How the data were processed

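RNA from 6 sorted cell samples was measured on Affymetrix arrays, 3 of Ebf2-GFP positive and 3 of Ebf2-GFP negative cells, all sorted for PDGFRα from the dorsal body wall of mouse embryos at stage E14.5. Per the labels' protocols, embryos were digested with collagenase and dispase, filtered, stained and sorted, and total RNA was extracted with TRIzol and a column kit and labelled with biotin. The deposited values are log2 expression values per probe set, for which the submitters' processing notes name RMA and limma. Their versions, the library files and any filter are not given in the sources used here. That the scale is log2 was read from the values, which ran from 3.41 to 14.32 with array medians between 6.657 and 6.712, as RMA output does. RMA sets the arrays to a common distribution, so a shift shared by most genes would not appear.

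Of 41345 probe sets, 190 were control probe sets. The platform table used here lists 1 gene for 23521 probe sets, several genes for 1814 and none for 15820, and genes were named only from the first kind. Symbols were updated by gene identifier through a table of RefSeq genes of assembly GRCm38.p6, which was also used for chromosomes and gene order. The deposited values carry no coordinates or genome build, so no positions are given. For a gene with several probe sets (1082 genes), the probe set with the highest mean over all 6 arrays was used. No gene had probe sets that passed in opposite directions (0 of 1082). This left 22180 genes, with no filter on dim probe sets. The files carry no detection calls, and the 40th percentile of gene means (log2 6.78) served as a mark of dim genes.

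The comparison was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the log2 values of all 6 arrays, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Changes are GFP-positive minus GFP-negative, errors beside group means are SD over 3 arrays, and those beside log2 changes are limma's moderated standard errors. The method was tested on simulated data made from the 22180 genes with 200 changed genes in each of 10 runs. It recovered 72.7% of genes changed by 0.5 on the log2 scale, 97.1% of those changed by 1 and 99.7% of those changed by 2, and 5.4% of its calls were false.

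A total of 26 gene lists with 566 entries were fixed before the data were examined, and 530 entries were measured. The other entries were not analysed here. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists, and with an estimated correlation none of the calls held. In simulated data, a shift of −0.5 in the cartilage list was called in 20 of 20 runs, with 3 of 500 calls among unchanged lists. In both simulations the genes varied independently and the arrays were not paired. The estimated correlations of the measured lists ran from −0.063 to 0.819. The simulation therefore does not measure false calls for lists whose genes vary together. Named genes follow a rule also fixed before the data were examined: Ebf2 and Pdgfra, the 12 largest increases and the 12 largest decreases among genes that passed and separated the arrays of the groups, up to 4 members with the smallest p from each list, and list members given where they did not share a list's direction. Other genes are said to have been chosen after their values were seen. Hoxa5 is named as the highest point of the Hox plot, Hoxc10 as a Hox gene outside the Hox list and Comp as a gene that correlated with the macrophage list, and these 3 were likewise chosen after their values were seen.

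Arrays of one group correlated at 0.9951 to 0.9969 over genes and arrays of different groups at 0.9845 to 0.9911. The first principal component held 62.7% of the variance and separated the groups. The labels number the replicates alike in both groups without saying what a number shares. Deviations from the group means of same-numbered arrays correlated at 0.314 to 0.519, and those of differently numbered arrays of the other group at −0.384 to −0.024. All 6 of 6 arrays correlated best with their own number. Such deviations cancel out within each group, so these correlations depend on each other and some must be positive. The 6 arrays are therefore not 6 separate agreements, and such a match can arise by chance. The numbers were still taken to pair the arrays, on this evidence of the data alone. The fit with the replicate number as a block is given where it changes a call or moves a count by over 1.5 times. Calls that pass only with the block depend on this inferred pairing. The labels give no scan date or batch.

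The alternatives were the replicate block, quantile normalization, median centring, leaving out dim probe sets, averaging or separately testing a gene's probe sets, eBayes with a trend or robust, array weights, stricter thresholds, camera with an estimated correlation, fry, and leaving out each array in turn. The plots were drawn with matplotlib.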

Results

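Gene expression was measured on 6 Affymetrix arrays of fibroblasts isolated from the dorsal body wall of 129SV mouse embryos at stage E14.5. The embryos were heterozygous for a green fluorescent protein (GFP) reporter of Ebf2, a transcription factor of the early B cell factor family. The dissociated cells were sorted for PDGFRα, a surface receptor of mesenchymal cells, and were then divided by GFP into an Ebf2-GFP positive group (n = 3 arrays) and an Ebf2-GFP negative group (n = 3 arrays). The comparison asked how, among PDGFRα-positive cells, the GFP-positive ones differ from their GFP-negative neighbours. The series describes Ebf2 as marking precursors of thermogenic fat cells. Each array gave log2 values for 41345 probe sets, with array medians between 6.657 and 6.712. The number of arrays limits the precision. The labels do not say whether replicates came from separate litters, so the p-values measure only the spread between these samples, which may be technical.

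Ebf2 followed the sort. Its mean log2 level was 12.0 ± 0.061 (SD, n = 3) in GFP-positive cells and 8.65 ± 0.526 (SD, n = 3) in GFP-negative cells, a 10.2-fold difference (log2 change 3.35 ± 0.24 SE, limma adjusted p = 0.000916). The GFP-negative arrays lay between 8.16 and 9.21, above the 40th percentile of all genes at 6.78. The files carry no detection calls, so a fold against a mean below that mark could be a lower bound. Another Ebf2 probe set, with a mean log2 level of 5.33, differed by 0.03 (limma adjusted p = 0.823 with each probe set tested by itself). Pdgfra, which was selected for in both groups, was at 13.1 ± 0.090 (SD, n = 3) and 12.9 ± 0.043 (SD, n = 3), and its log2 change of 0.19 ± 0.06 SE did not pass the test (adjusted p = 0.178).

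Of 22180 genes tested, 1439 passed limma's test at the adjusted p threshold of 0.05, of which 588 were higher and 851 lower in GFP-positive cells. At least 2-fold differences were found for 78 higher and 308 lower genes. All 1439 genes separated the 3 arrays of one group from the 3 of the other, which follows largely from passing the test. Among all genes tested, these included, 4890 did so (22%, where chance gives 10% if the arrays are not paired). With the replicate number as a block, 2228 genes passed, 1010 higher and 1218 lower, and 1395 of them had also passed without the block. After centring each array on its median, 868 genes were higher and 749 lower, so that the higher genes made up 53.7% of the calls in place of 40.9%. Without positive replicate 1, 2 or 3 the count was 629, 667 or 762.

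The largest increase was that of Gpr83, an orphan G protein-coupled receptor, which rose 10.6-fold (log2 change 3.41 ± 0.08 SE, adjusted p = 4.54e-05). Rxfp2, the receptor of insulin-like peptide 3, was 9.82-fold higher (3.30 ± 0.16 SE, adjusted p = 0.000322), and its mean in GFP-negative cells (6.59) lay below the 40th percentile of all genes, as did that of Cilp (6.40). Phex, an endopeptidase of phosphate homeostasis that is best known from bone, rose 5.43-fold (adjusted p = 0.000609). Meox1, a homeobox gene of the somite, rose 4.67-fold (adjusted p = 0.00323). The 12 largest increases also held Ebf2, on which the cells were sorted, Lhfpl1 (5.34-fold), the lipid kinase gene Dgkk (4.43-fold) and the chemokine gene Cxcl9 (4.15-fold). The remaining ones were the matrix genes Cilp (4.13-fold) and Tnxb (3.74-fold), the cation channel gene Trpc5 (3.71-fold) and the neurotrophin receptor gene Ngfr (3.60-fold). The call of Tnxb ended without negative replicate 1 or 2 or any 1 positive replicate, with adjusted p-values of up to 0.136 over the arrays left out.

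The 12 largest decreases were led by F13a1, which encodes the A subunit of coagulation factor XIII (11.5-fold, log2 change −3.52 ± 0.47 SE, adjusted p = 0.00822). It was followed by the mannose receptor gene Mrc1 (10.1-fold, −3.34 ± 0.49 SE, adjusted p = 0.0114) and by Adgre1, a macrophage marker (9.94-fold, −3.31 ± 0.46 SE, adjusted p = 0.00923). The others were Cxcl2, Lix1, Lilrb4a, Slc7a11, Cemip, Lyve1, Ms4a6d, Pld4 and Hpgds, with log2 changes between −3.18 and −2.97. The means of Slc7a11, Ms4a6d and Hpgds in GFP-positive cells lay below the 40th percentile. Between arrays of one group, 9 of the 12 genes correlated with the mean of the macrophage list at r above 0.9, among them Mrc1 and Adgre1, which are members of that list (7 of 10 without them). The other 3 were Lix1 (−3.18 ± 0.24 SE, adjusted p = 0.000996), the cystine transporter gene Slc7a11 (−3.04 ± 0.22 SE, adjusted p = 0.000969) and Cemip, a gene of hyaluronan breakdown (−3.03 ± 0.26 SE, adjusted p = 0.00161), at r of −0.649, 0.639 and 0.571 over the 6 arrays. Leaving out 1 array ended the calls of Mrc1 (adjusted p = 0.0511 without negative replicate 1) and Lyve1 (0.0517 without positive replicate 2). The calls of Cxcl2 and Ms4a6d ended without negative replicate 1 or 3 or positive replicate 2 (adjusted p up to 0.0641 and 0.0724). That of Pld4 ended without negative replicate 1 or positive replicate 1 or 2 (up to 0.0552), and that of Lilrb4a without any 1 negative replicate or positive replicate 2 (up to 0.08).

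**Figure D1:**
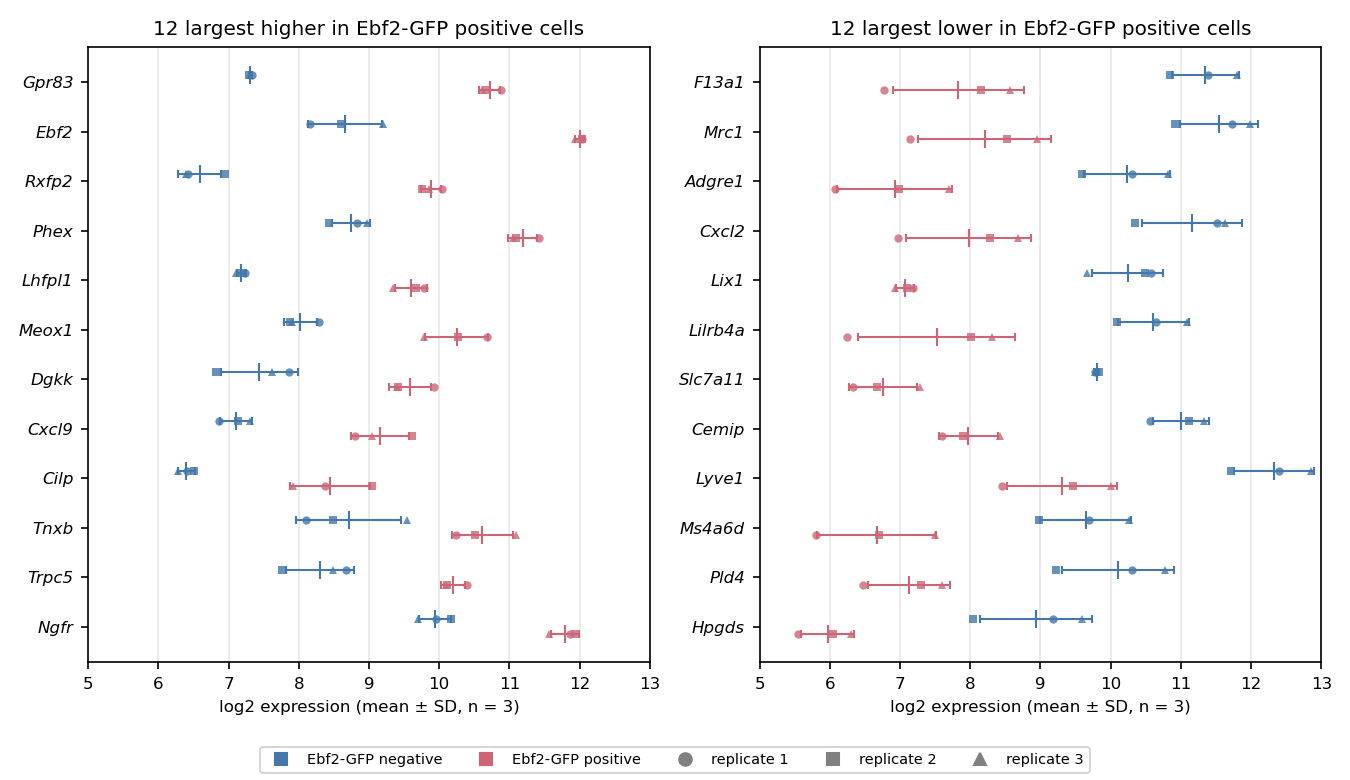
Log2 expression (x axis) of the 12 genes with the largest increases (left) and the 12 with the largest decreases (right) in Ebf2-GFP positive cells, with each array as a point shaped by replicate and each group's mean ± SD (n = 3). Gpr83 lay at 7.31 in negative and 10.7 in positive cells, and F13a1 at 11.3 and 7.83.

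Genes of brown and beige fat did not move together. Of 28 measured members of the brown and beige adipocyte list, 1 was higher and 1 lower (1 and 3 adjusted over the list alone, 2 and 3 with the replicate block), and the list did not pass camera's test (adjusted p = 0.565). Its median change was 0.013 on the log2 scale, whereas its mean (−0.044) and the test pointed to lower values. Ppargc1a, a coactivator of mitochondrial biogenesis, was 1.5-fold higher (0.59 ± 0.13 SE, adjusted p = 0.0462), and Zic1, a zinc finger gene used as a marker of brown fat, was 2-fold lower (SE of the log2 change 0.09, adjusted p = 0.00202). The call of Ppargc1a ended without any 1 negative replicate and without positive replicate 1 or 2, with adjusted p-values of up to 0.17. Chosen after their values were seen, Ucp1, the uncoupling protein of brown fat, and Prdm16, a regulator of brown fat identity, had log2 changes of 0.03 ± 0.05 SE (adjusted p = 0.818) and −0.26 ± 0.12 SE (adjusted p = 0.341). The mean log2 level of Ucp1 in GFP-negative cells was 5.84, and 10 of the 28 list members lay below the 40th percentile of all genes.

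The general adipogenic list held 24 measured members, none of which passed limma's test (0 adjusted over the list alone, 5 at an unadjusted p under 0.05, 1 higher and 1 lower with the block). Its median log2 change was 0.088 (−0.001 to 0.138 with 1 array left out), with a camera adjusted p of 0.242. Without negative replicate 3 or positive replicate 1 the list passed, and its adjusted p ranged from 0.0215 to 0.93 over the arrays left out. Pparg and Fabp4, also chosen after their values were seen, differed by 0.58 ± 0.31 SE (adjusted p = 0.417) and 0.78 ± 0.51 SE (adjusted p = 0.516), and each was higher in the GFP-positive array in 3 of 3 replicate pairs. Fabp4 passed with the replicate block (adjusted p = 0.0224), and Pparg did not. Cebpa, another regulator of adipogenesis, had a log2 change of 0.37 ± 0.11 SE (adjusted p = 0.123). In the list of white adipose and preadipocyte genes, 1 of 15 measured members was higher and 0 lower (1 and 1 adjusted over the list alone, 1 and 2 with the block, camera adjusted p = 0.565). The higher gene was Wt1, a zinc finger gene of mesothelium and visceral fat precursors, which rose 1.70-fold (0.76 ± 0.10 SE, adjusted p = 0.00863).

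**Figure D2:**
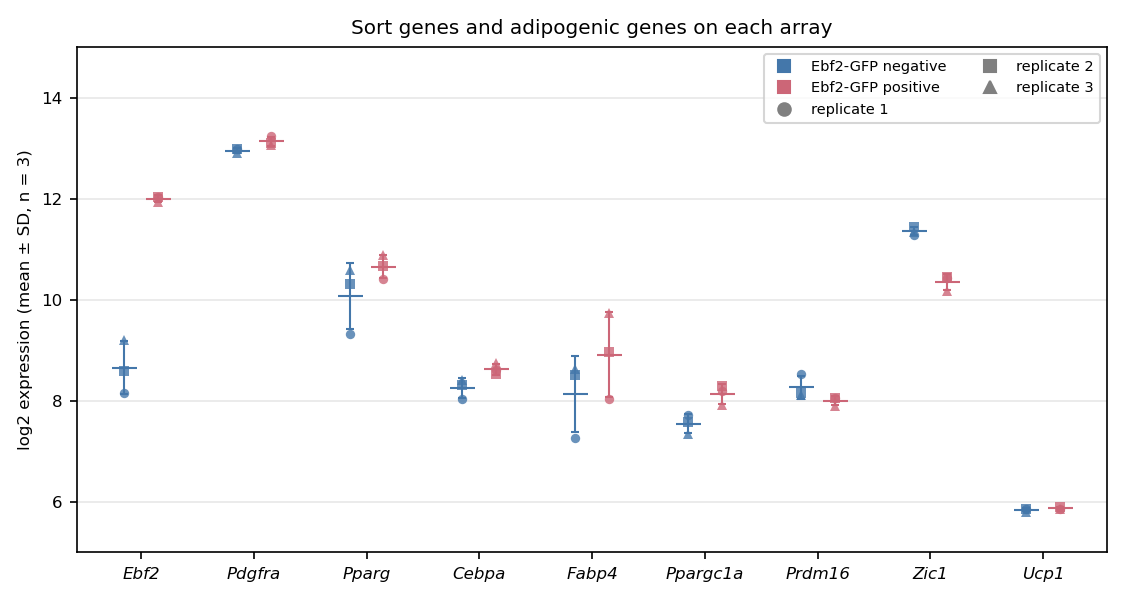
Log2 expression (y axis) of the sort genes Ebf2 and Pdgfra and of 7 adipogenic genes on each array, with points shaped by replicate and each group's mean ± SD (n = 3). The Ebf2 arrays separated by 3.35 on the log2 scale between group means, and the Pparg and Fabp4 arrays of the groups overlapped.

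In the Ebf family list, 2 of 6 measured members were higher and 0 lower (3 and 2 adjusted over the list alone, 3 and 1 with the block), and the list did not pass (camera adjusted p = 0.0913, or 0.0274 without negative replicate 3 and 0.0139 with fry). The list holds Ebf2, on which the cells were sorted, so its tests partly restate the sort, and it was not tested without Ebf2. The members that rose were Ebf2 itself and Ebf3, which was 2.03-fold higher (1.02 ± 0.11 SE, adjusted p = 0.00359). Ebf4 and Zfp521 had log2 changes of −0.32 and −0.25 and did not pass (limma adjusted p = 0.134 and 0.0929). Zfp423, a preadipocyte zinc finger gene, had a log2 change of 0.39 ± 0.09 SE (adjusted p = 0.0612). It passed with the replicate block (0.0445), without negative replicate 3 (0.0308), after quantile normalization (0.0346), after median centring (0.0371) and without dim probe sets (0.0435), and its highest adjusted p over all these settings and arrays left out was 0.205.

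Cartilage genes were lower in GFP-positive cells. Of 26 measured members, 22 fell and none rose (23 and 0 adjusted over the list alone), with a median log2 change of −1.236 (camera adjusted p = 3.68e-29). With an estimated correlation the call was lost (adjusted p = 0.11). The smallest p-value was that of the matrix gene Matn3, which fell 4.59-fold (−2.20 ± 0.08 SE, adjusted p = 0.000171). Hapln1, a link protein of hyaluronan, fell 3.99-fold (SE of the log2 change 0.12, adjusted p = 0.000527). The collagen IX genes Col9a3 and Col9a1 fell 3.97-fold (−1.99 ± 0.11 SE, adjusted p = 0.000405) and 3.79-fold (−1.92 ± 0.12 SE, adjusted p = 0.000527). Macrophage genes were lower in the same arrays, and between arrays of one group 1 of the 22 genes, Comp, correlated with them at r above 0.9. The call of Comp (adjusted p = 0.0338) ended without any 1 array other than positive replicate 3 (up to 0.124). Bone and osteoblast genes also fell, with 4 of 13 measured members lower and 1 higher (6 and 1 adjusted over the list alone), a median of −0.320 and a camera adjusted p of 0.000961 (adjusted p = 0.11 with an estimated correlation). The median was −0.099 without negative replicate 1, where the list still passed (adjusted p = 0.00167). The osteoblast transcription factor gene Sp7 was 1.98-fold lower (−0.99 ± 0.09 SE, adjusted p = 0.00205) and Omd 1.79-fold lower (−0.84 ± 0.06 SE, adjusted p = 0.00116), against the rise of Phex. The mean of Omd in GFP-positive cells lay below the 40th percentile.

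Dermal fibroblast genes fell, with 14 of 23 measured members lower and none higher (15 and 1 adjusted over the list alone), a median of −0.618 and a camera adjusted p of 1.55e-14. The call was lost with an estimated correlation (adjusted p = 0.11). Dkk1, a secreted Wnt inhibitor, fell 4.31-fold (−2.11 ± 0.12 SE, adjusted p = 0.00047) and Axin2, a Wnt target, 2.32-fold (−1.21 ± 0.08 SE, adjusted p = 0.000602). The transcription factor genes Msx2 and Twist1 fell 1.89-fold and 1.75-fold (adjusted p = 0.000551 and 0.000969). In the Wnt signalling list, 11 of 27 measured members were lower and 7 higher (14 and 7 adjusted over the list alone), with a median of −0.257 (camera adjusted p = 0.00241, adjusted p = 0.11 with an estimated correlation). The lower members included Apcdd1 (3.38-fold, −1.76 ± 0.10 SE, adjusted p = 0.000395), Sfrp5 (2.61-fold, adjusted p = 0.000808) and Notum (1.90-fold, adjusted p = 0.00105), which are known as secreted or membrane inhibitors of the pathway. The means of Dkk1, Msx2, Sfrp5 and Notum in GFP-positive cells lay below the 40th percentile. Tcf7l2, a transcription factor of the pathway, was 1.75-fold higher (0.80 ± 0.06 SE, adjusted p = 0.00116), and the list's direction was also not shared by Rspo2, a secreted Wnt enhancer (1.14 ± 0.10 SE, adjusted p = 0.00205).

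All 16 measured leukocyte and macrophage genes were lower in GFP-positive cells (16 adjusted over the list alone), with a median log2 change of −2.358 (camera adjusted p = 4.19e-18). With an estimated correlation the call was lost (adjusted p = 0.187). Besides Adgre1 and Mrc1, the growth factor receptor gene Csf1r fell 7.18-fold (−2.84 ± 0.37 SE, adjusted p = 0.00766). The lysozyme gene Lyz2 fell 4.99-fold (−2.32 ± 0.33 SE, adjusted p = 0.0104, or 0.0563 without positive replicate 2) and the actin-binding gene Coro1a 1.92-fold (−0.94 ± 0.11 SE, adjusted p = 0.0045). The mean log2 level of the list was 9.94, 9.39 and 10.33 in negative replicates 1, 2 and 3, and 7.10, 7.85 and 8.11 in positive replicates 1, 2 and 3. Of the list's own 16 members, 11 correlated with that mean within groups at r above 0.9. Lyz2 and Coro1a were among the 5 that did not, so this limit misses some genes of the list itself. With the 16 members left out, 82 of the other 835 lower genes (9.8%) were above it. So were 59 of the other 293 at least 2-fold lower genes (20.1%), 2 of the 588 higher genes and 253 of the 20741 genes that did not pass (1.2%). In the lists of other cell types and pathways, the lower genes above that limit were 0 of 14 dermal, 0 of 11 Wnt, 0 of 4 bone, 1 of 22 cartilage (Comp), 1 of 5 mural (Rgs5) and 1 of 5 TGF beta and BMP genes (Bmp6), and 0 in the remaining lists.

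**Figure D3:**
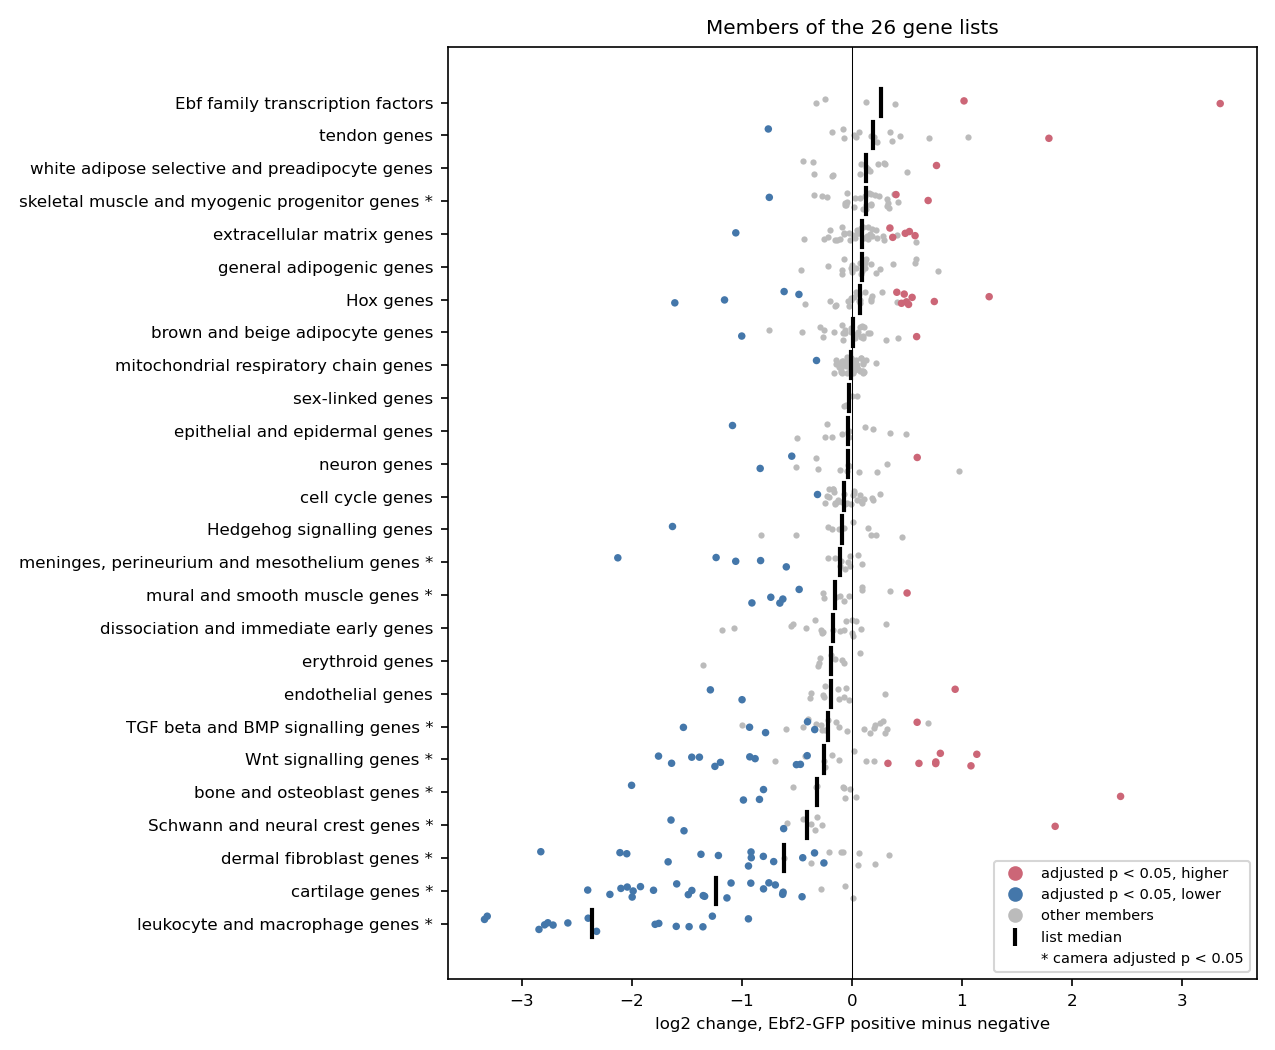
Log2 change between Ebf2-GFP positive and negative cells (x axis) of each measured member of the 26 gene lists (rows, ordered by median), with members past the adjusted p threshold of 0.05 in colour, black bars for medians and asterisks for lists past camera's test. The medians of the leukocyte and macrophage, cartilage and dermal fibroblast lists lay at −2.358, −1.236 and −0.618.

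Mural and smooth muscle genes fell, with 5 of 15 measured members lower and 1 higher (6 and 1 adjusted over the list alone, 4 and 2 with the block), a median of −0.149 and a camera adjusted p of 0.00257 (adjusted p = 0.11 with an estimated correlation). The median was −0.083 without positive replicate 1 and −0.092 after median centring. The contractile genes Cnn1 and Acta2 were 1.88-fold and 1.54-fold lower (adjusted p = 0.00106 and 0.0045). In the list of meninges, perineurium and mesothelium, 5 of 15 measured members fell and none rose (5 and 0 adjusted over the list alone), with a median of −0.107 and a camera adjusted p of 0.000271 (adjusted p = 0.11 with an estimated correlation). The median was −0.011 without negative replicate 2, −0.178 without negative replicate 1, −0.164 without negative replicate 3 and −0.176 without positive replicate 2. It was −0.051 after median centring and −0.219 without dim probe sets. They included Ptgds, a prostaglandin D2 synthase (4.37-fold, −2.13 ± 0.25 SE, adjusted p = 0.00535), Zic2 (2.35-fold, −1.23 ± 0.10 SE, adjusted p = 0.00122) and Foxc2 (2.08-fold, −1.06 ± 0.08 SE, adjusted p = 0.00126). In the Schwann and neural crest list, 3 of 10 measured members fell and 1 rose (7 and 1 adjusted over the list alone), with a median of −0.406 and a camera adjusted p of 0.000244 (adjusted p = 0.149 with an estimated correlation). Fabp7 fell 3.12-fold (−1.64 ± 0.22 SE, adjusted p = 0.00802), whereas Ngfr, which is also expressed outside the nervous system, rose.

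Skeletal muscle and myogenic genes passed narrowly, with 2 of 30 measured members higher and 1 lower (3 and 1 adjusted over the list alone, 5 and 1 with the block), a median of 0.129 and a camera adjusted p of 0.0496 (adjusted p = 0.638 with an estimated correlation). The call ended without negative replicate 1 (adjusted p = 0.265), positive replicate 2 (0.415) or positive replicate 3 (0.0632), after median centring (0.0869), without dim probe sets (0.0699) and with fry (0.357). The median was 0.035 without negative replicate 1 and 0.211 without negative replicate 2. Tnnt1, a troponin of slow muscle, was 1.32-fold higher (0.40 ± 0.06 SE, adjusted p = 0.00917). In the TGF beta and BMP list, 5 of 27 measured members were lower and 1 higher (10 and 3 adjusted over the list alone, 9 and 4 with the block), with a median of −0.214 and a camera adjusted p of 0.0234 (adjusted p = 0.349 with an estimated correlation). That call ended without negative replicate 1 (adjusted p = 0.0874) or positive replicate 3 (0.0526), and the median was −0.116 without negative replicate 2. Tgfb1 fell 2.89-fold (−1.53 ± 0.13 SE, adjusted p = 0.0015) and Bmp6 1.91-fold (−0.93 ± 0.10 SE, adjusted p = 0.00398), while Chrd, which encodes the BMP antagonist chordin, rose 1.51-fold (0.59 ± 0.08 SE, adjusted p = 0.00676). Within groups Bmp6 correlated with the mean of the macrophage list at r = 0.947.

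A further 4 lists did not pass without the replicate block but did with it, and 3 of them also passed in other settings with all 6 arrays. Tendon genes had 1 of 16 measured members higher and 1 lower (3 and 1 adjusted over the list alone, 4 and 1 with the block), a median of 0.189 and a camera adjusted p of 0.0645 (0.0203 with the block). Thbs4, a thrombospondin of tendon, rose 3.46-fold (1.79 ± 0.14 SE, adjusted p = 0.00116), and Tnmd, the tenomodulin gene, had a log2 change of 1.05 ± 0.29 SE (adjusted p = 0.0974, 0.0143 with the block). Endothelial genes had 1 of 14 measured members higher and 2 lower (1 and 2 adjusted over the list alone), a median of −0.186 and a camera adjusted p of 0.0512 (0.00212 with the block). Erg, an endothelial transcription factor gene, fell 2.44-fold (−1.29 ± 0.11 SE, adjusted p = 0.00169), whereas Emcn, which encodes endomucin, rose 1.92-fold (0.94 ± 0.16 SE, adjusted p = 0.0214, up to 0.0943 without negative replicate 3 or any 1 positive replicate). None of 9 measured erythroid genes passed limma's test (0 adjusted over the list alone, 1 at an unadjusted p under 0.05), with a median of −0.186 and a camera adjusted p of 0.0645 (0.0203 with the block). None of 19 dissociation and immediate early genes passed either (0 adjusted over the list alone, 1 at an unadjusted p under 0.05). With the block, 1 of them was higher and 6 lower, and the list had a median of −0.173 and a camera adjusted p of 0.0726 (0.000468 with the block). None of these 4 lists passed with an estimated correlation (adjusted p = 0.638 for each). The tendon list passed without negative replicate 2 or positive replicate 1 or 3 (adjusted p from 0.0133 to 0.427 over the arrays left out). The endothelial list passed without negative replicate 1 or 3 or positive replicate 2 (0.00827 to 0.707), after median centring (0.00688) and with a gene's probe sets averaged (0.0499). The erythroid and dissociation lists passed without negative replicate 1 or positive replicate 2 (0.00518 to 0.351 and 0.000965 to 0.325) and after median centring (0.0212 and 0.0219), and the dissociation list after quantile normalization (0.0351). With 1 array left out the tendon median ranged from 0.097 (without negative replicate 1 or positive replicate 2) to 0.216 (without negative replicate 2). The endothelial median ranged from −0.371 (without negative replicate 1) to −0.023 (without negative replicate 2). The erythroid median ranged from −0.312 (without positive replicate 2) to −0.074 (without positive replicate 1), and the dissociation median from −0.351 (without positive replicate 2) to −0.03 (without negative replicate 2).

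Hox genes changed in both directions. Of 33 measured members, 8 were higher and 4 lower (12 and 5 adjusted over the list alone), with a median of 0.071 (0.037 to 0.128 with 1 array left out) and a camera adjusted p of 0.118 (0.0298 without negative replicate 1, 0.0384 after quantile normalization and 0.0486 without dim probe sets). Hoxd8 fell 3.05-fold (−1.61 ± 0.10 SE, adjusted p = 0.000565) and Hoxb9 2.23-fold (−1.16 ± 0.13 SE, adjusted p = 0.00392), whereas Hoxa4 rose 1.68-fold (0.75 ± 0.07 SE, adjusted p = 0.00218). Hoxa5 rose most (1.25 ± 0.21 SE, adjusted p = 0.0192), a call that ended without any 1 array other than negative replicate 1 (up to 0.0892). The 3 other measured Hox genes, Hoxc8, Hoxc9 and Hoxc10, are in the white adipose and preadipocyte list and did not pass (adjusted p = 0.131, 0.0683 and 0.257). Hoxc9 passed with the replicate block (0.0166), without dim probe sets (0.0487) and without negative replicate 3 (0.0425). Hoxc10 also passed with the block (0.0211). In the extracellular matrix list, 5 of 38 measured members were higher and 1 lower (8 and 3 adjusted over the list alone, 7 and 2 with the block), with a median of 0.095 (0.058 to 0.108 with 1 array left out) and a camera adjusted p of 0.0709 (between 0.014 and 0.465 with 1 array left out, and past the threshold without negative replicate 3 or positive replicate 1). Col4a1 and Col6a3 rose 1.49-fold and 1.44-fold (adjusted p = 0.00832 and 0.00776), and Col8a1 fell 2.08-fold (−1.05 ± 0.10 SE, adjusted p = 0.00204).

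**Figure D4:**
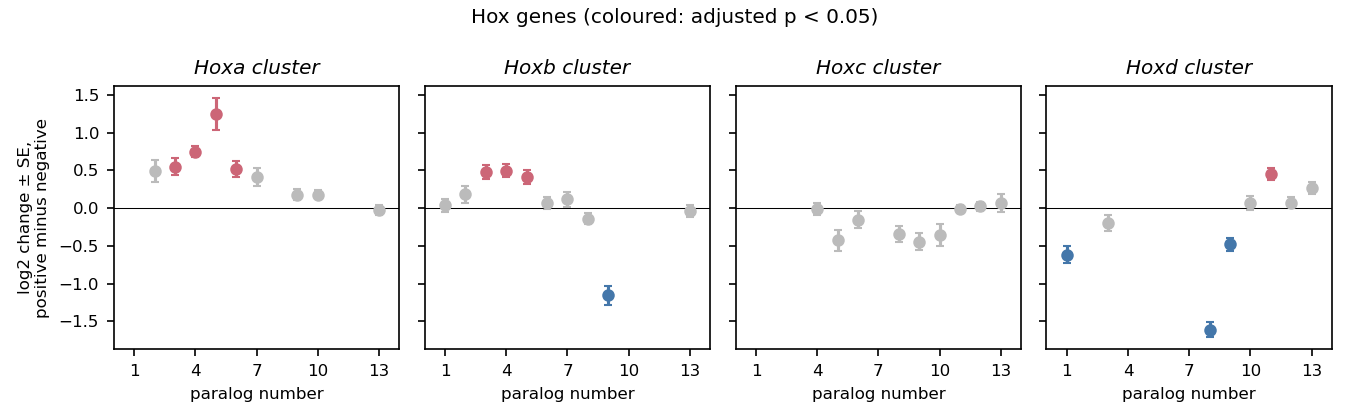
Log2 change ± SE between Ebf2-GFP positive and negative cells (y axis) of all 36 measured Hox genes (33 of the Hox list and 3 of another list) by paralog number (x axis) in the 4 clusters, with genes past the adjusted p threshold in red (higher) or blue (lower) and the others in grey. Hoxd8 lay lowest at −1.61 and Hoxa5 highest at 1.25.

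Proliferation and respiratory chain genes differed little. Of 28 measured cell cycle genes, 0 were higher and 1 lower (0 adjusted over the list alone), with a median of −0.067 (−0.104 to −0.04 with 1 array left out) and a camera adjusted p of 0.118 (0.0212 without positive replicate 2 and 0.0383 after quantile normalization). The lower gene was Cdc20 (−0.32 ± 0.06 SE, adjusted p = 0.0356), whose call ended after median centring (0.0611) and without any 1 array other than positive replicate 2 (up to 0.135). Of 55 measured mitochondrial respiratory chain genes, 0 were higher and 1 lower (0 adjusted over the list alone), with a median of −0.008 and a camera adjusted p of 0.403. That gene was Atp5g2 (−0.33 ± 0.07 SE, adjusted p = 0.0361), whose call ended after median centring (0.0564) and without any 1 of the 6 arrays (0.0534 to 0.136). Hedgehog signalling genes had 1 of 12 measured members lower and 0 higher (3 and 3 adjusted over the list alone, 2 and 1 with the block), with a camera adjusted p of 0.273 (0.0371 without negative replicate 3). The lower gene was Foxf2, a forkhead gene, which fell 3.10-fold (−1.63 ± 0.22 SE, adjusted p = 0.00815), with a mean in GFP-positive cells below the 40th percentile. Of 14 measured neuron genes, 1 was higher and 2 lower (3 and 5 adjusted over the list alone, 3 and 4 with the block, camera adjusted p = 0.326). Of 13 measured epithelial genes, 0 were higher and 1 lower (0 and 1 adjusted over the list alone, 1 and 1 with the block, camera adjusted p = 0.207). The epithelial member was the cadherin gene Cdh1 (2.13-fold lower, −1.09 ± 0.09 SE, adjusted p = 0.00161). None of 4 measured sex-linked genes passed limma's test (0 adjusted over the list alone and 0 at an unadjusted p under 0.05, camera adjusted p = 0.677). Xist, which is expressed from the inactive X chromosome, was at 12.2 in both groups.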

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

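The comparison of endothelial with leukocyte genes, the slope of cartilage on macrophage genes, the correlations with the replicate block and the test of the embryos' sex ratio were chosen only after the results were seen. Probe sets to which no gene or several genes are assigned lie outside the comparison, and some of them differed between the groups while 0 of the 190 control probe sets did (limma, 2 at an unadjusted p under 0.05). In a fit over all 41345 probe sets, 70 of 15820 probe sets with no gene listed passed (0.44%), 39 higher and 31 lower in GFP-positive cells, with log2 changes of up to 2.01 and down to −2.61. Of 1814 probe sets listing several genes, 19 passed (1.05%), 10 higher and 9 lower, with changes of up to 0.95 and down to −1.83. Among the 23521 probe sets with 1 gene, 719 passed (3.06%), against 1414 when they were fitted by themselves. Groups of 3 arrays were not tested for outliers.

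The 6 arrays can be divided into 3 and 3 in 10 ways, which is too few for a share under 0.05. Only 1 of the 10, the division by GFP, gave 1439 genes (3927 at an unadjusted p under 0.05), and the highest count in the others was 0 (limma, 223 to 1422 at an unadjusted p under 0.05). The division by GFP parts all 3 same-numbered pairs. The 3 other divisions that do so gave 0 genes (limma, 223 to 278 at an unadjusted p under 0.05), and the 6 that part 1 pair gave 0 as well (664 to 1422). All divisions other than that by GFP mix GFP-positive and GFP-negative arrays on both sides. The difference by GFP then adds to the spread within each side and lowers the count, so these counts do not show what chance gives.

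Macrophage genes were lower in all 3 GFP-positive arrays, although a sort for PDGFRα would be expected to remove macrophages from both groups. An equal fall in the share of all cells other than fibroblasts is argued against. Endothelial genes would then have fallen alike, and their median log2 change lay 2.172 above that of the leukocyte list (95% bootstrap interval over genes 1.408 to 2.642). This interval takes genes as independent, though those of each list varied together. With 1 array left out, medians ranged from −0.371 to −0.023 for endothelial and −2.669 to −2.102 for leukocyte genes. The erythroid median was −0.186, with 5 of 9 genes below the 40th percentile. Unequal falls are not excluded, and the mural and Schwann lists also fell. The endothelial list itself was lower with the replicate block (camera adjusted p = 0.00212). Its genes Erg and Cdh5 were lower also without the block, while Emcn was higher. A smaller share of macrophages in the GFP-positive sort is a candidate explanation. Between arrays of one group the 16 genes moved together, with a median pairwise correlation of 0.842, against −0.129 to 0.227 (95% range) for random lists matched on level. With the replicate block it was 0.894 (random lists −0.207 to 0.332). The highest array signals of the list in GFP-negative cells were those of Fcer1g, C1qb and Mrc1 (log2 11.8, 11.6 and 11.5), the first 2 named after their values were seen. Probe sets differ in affinity, so this order does not rank transcripts. The call of C1qb (adjusted p = 0.0184) ended without negative replicate 1 or 3 or positive replicate 2 (up to 0.0723), and that of Mrc1 without negative replicate 1 (0.0511). None of the 16 genes is in another list, and 14 of the 16 lay above the 40th percentile in GFP-positive cells too. Whether macrophages entered the negative gate in sorting or lie with GFP-negative cells in the tissue remains open, and neither was tested.

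Cartilage genes were lower in GFP-positive cells, 22 of 26 past the threshold. Whether the cells or RNA that carried the macrophage genes are the reason remains open. The changes between groups would need the cartilage mean to move by 0.554 per unit of the macrophage mean. Within groups it moved by 0.132 (95% interval −0.186 to 0.45), which lies below that, but this fit leaves out the inferred pairing of the arrays. Within groups and pairs it moved by 0.27 (−1.219 to 1.76), with 1 residual degree of freedom, which does not decide. A smaller share of cartilage-forming cells and a lower expression per cell cannot be told apart. The cartilage genes' median pairwise correlation within groups was 0.371, above the 95% range of random lists (−0.069 to 0.189) and below the 0.5 set beforehand as the mark of a varying share. With the replicate block it was 0.637 (random lists −0.133 to 0.24), above that mark, so the 2 fits differ. All 26 genes lay above the 40th percentile in both groups, and none is in another list.

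Of the 12 largest increases, 4 (Phex, Lhfpl1, Dgkk and Trpc5) are genes of the X chromosome. As a hypothesis tested on the same data, X-linked genes may be over-represented among the higher genes. Of 905 tested X-linked genes, 46 were higher (5.08%) against 2.56% elsewhere. The odds ratio was 2.04 (95% interval 1.47 to 2.79, Fisher's exact test, two-sided, p = 2.98e-05, adjusted p = 0.00119 over 40 tests of 20 chromosomes in both directions). It lay between 1.63 and 2.08 with the replicate block, without dim probe sets and after median centring or quantile normalization. Fisher's test takes genes as independent, but Lhfpl1, for example, lies in a run of 3 neighbouring higher genes. The interval and p may therefore be too narrow. Whether a different sex ratio of the embryos is a reason is not decided for the smaller X-linked rises, which went down to 0.28 on the log2 scale. For these the fits with and without the block differ. With the block, Xist and the measured Y-linked genes differed by at most −0.069 on the log2 scale, or 0.217 when widened by 2 standard errors. This lies under the limit of 0.3, which was set after the results were seen. The pairs behind the block were inferred from these same arrays. Without the block the changes were the same, but that of Xist (−0.052) widened to 0.333, past the limit. A sex ratio alone would be expected to move other genes no further than Xist and the Y-linked genes. The log2 changes of Phex, Lhfpl1, Dgkk and Trpc5 (2.44, 2.42, 2.15 and 1.89) lay far beyond 0.333, which argues against it for these 4 genes. What sets these genes apart remains open, and no other biological explanation was tested.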

How the results depend on the processing

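The alternatives were chosen before the data were examined. The count of 1439 genes lay between 1394 and 1617 under quantile normalization, median centring, the filter on dim probe sets, other rules for probe sets, a trended or robust eBayes and array weights. It was 2228 with the replicate block, 539 at an adjusted p under 0.01 and 386 with at least a 2-fold change. With 1 array left out it was 629 to 1067, lowest without positive replicate 1 (629), 2 (667) and 3 (762). In the fit over all 41345 probe sets, 719 of the 23521 with 1 gene passed, against 1414 when these were fitted without the others. The count therefore depends on which probe sets share the fit. The stricter thresholds and the smaller number of arrays go with fewer genes by construction. For the block and the fit over all probe sets the cause was not tested. Of the lists, 10 passed, and 14 with the block. With an estimated correlation 0 passed (camera, 7 at an unadjusted p under 0.05), against 10 with fry. With fry 9 were shared, the muscle list was lost and the Ebf list, which holds the sort gene Ebf2, was gained. The cause of these differences was not tested. Leaving out dim probe sets, which removes 10 of the 28 brown and beige genes, turned the direction of that list's test (median 0.063, not past the threshold). The other reversals were of genes and lists that passed in none of these settings, and the cause was not tested. Kdm5d was at 0.0174 after quantile normalization, 0.0557 after median centring and 0.0195 with array weights, and Xist at 0.004 after median centring. With 1 array left out, the log2 change ranged from −0.06 to 0.0685 for Kdm5d, −0.1541 to 0.0657 for Xist and −0.0174 to 0.1355 for Eif2s3y. Medians ranged from −0.025 to 0.015 for the mitochondrial list and −0.054 to 0.03 for the sex-linked list. Of 152 genes examined singly 107 passed, and 0 of these changed direction in any setting. With some array left out 34 lost the call, and at the same threshold 3 did in other settings (Cdc20 and Atp5g2 after median centring, Gbp4 with the block). The block changed no other call of a list or gene named in the text than those given beside their results. The planned exclusion of probe sets by the ending of their identifiers was not run, since these are plain numbers. For genes below the 40th percentile (log2 6.78), such as Ucp1, no detection calls tell signal from background.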

Other observations

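The gene families of the next 2 paragraphs, their members and the test of Hox genes by position were chosen only after the results were seen. A total of 12 families were looked at, and all are given.

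Irx homeobox genes fell, with 4 of 6 measured members lower, also with any 1 array left out. Irx1 was 7.09-fold, Irx2 5.14-fold, Irx5 3.47-fold and Irx3 3.28-fold lower in GFP-positive cells, with adjusted p-values of 0.00148, 0.000808, 0.000376 and 0.000658. All 4 measured Zic genes were lower, with a median log2 change of −0.915, and 3 without positive replicate 2 (Zic4, adjusted p = 0.0547). All 4 Sprouty genes, which encode feedback inhibitors of receptor tyrosine kinase signalling, were higher, but only 2 or 3 of them with 1 array left out. Spry4 rose 2.43-fold (1.28 ± 0.16 SE, adjusted p = 0.00708) and Spry1 1.83-fold (0.87 ± 0.12 SE, adjusted p = 0.00869, or 0.0503 without positive replicate 1). The call of Spry3 ended without negative replicate 2 or positive replicate 3 (adjusted p up to 0.0606), and that of Spry2 without any 1 array other than negative replicate 2 (up to 0.149). Of 5 measured A-subfamily lipid transporter genes, 4 rose, led by Abca8b (2.11-fold, adjusted p = 0.000676) and Abca8a (1.81-fold, adjusted p = 0.000969). The call of Abca9 ended without negative replicate 2 or any 1 positive replicate (up to 0.094). The soluble guanylate cyclase subunit genes Gucy1b1 and Gucy1a1 rose 2.61-fold and 1.74-fold (adjusted p = 0.00122 and 0.00836), and the other 2 measured subunit genes did not pass. These directions were the same after quantile normalization and median centring.

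The interferon-inducible chemokine gene Cxcl9 was the 1 of 3 measured CXCR3 ligand genes that was higher, with 0 lower, or 1 lower without negative replicate 2. Of 10 measured guanylate-binding protein genes, 3 were higher and 0 lower, but 2 and 1 with the replicate block, and 1 or 2 higher with 1 array left out. Gbp9 rose 1.71-fold (adjusted p = 0.00683). The call of Gbp8 (adjusted p = 0.0205) ended without negative replicate 3 or positive replicate 1 or 2 (up to 0.0861). That of Gbp4 (adjusted p = 0.0409) ended with the block (0.0515) and without any 1 array other than positive replicate 1 (up to 0.12). The means of Gbp8 in GFP-negative cells and of Gbp4 in both groups lay below the 40th percentile. Of 16 other interferon-inducible genes, 0 were higher and 2 lower, 1 and 1 after quantile normalization, and 0 lower without positive replicate 1 or 2. Toll-like receptor genes had 6 of 12 measured members lower and 0 higher (6 and 1 with the block), but 5 lower without negative replicate 2, 2 without negative replicate 3 and 1 without any 1 of the other 4 arrays. Ms4a genes had 5 of 20 lower and 0 higher (6 lower with the block), and 2 without negative replicate 1 or positive replicate 2. Macrophage genes fell in the same arrays, and these families were not shown to change apart from them. Of the lower genes, 3 of 6 Toll-like receptor genes and 4 of 5 Ms4a genes correlated with the macrophage mean within groups at r above 0.9, and the lowest r were 0.749 and 0.883. T-box genes had 1 of 13 higher and 1 lower (2 and 1 with the block, 0 lower after median centring), and between 0 and 2 higher with 1 array left out. Olfactory receptor genes had 3 of 1088 higher and 0 lower, 8 higher after median centring, 5 higher and 1 lower with the block, and 0 higher without positive replicate 1 or 2.

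A hypothesis was that GFP-positive cells may come on average from a more anterior part of the trunk, which would make the change of Hox genes fall with their paralog number. Over 36 measured Hox genes, Spearman's rho was −0.223 (permutation p = 0.192, two-sided) and Pearson's r −0.186 (permutation p = 0.284), or −0.28 without the 2 genes farthest from the median paralog number. Over the 28 genes of paralogs 1 to 10 rho was −0.353, which was not tested, and over all 36 it was below 0 in 3 of 3 replicate pairs. Neither passed, and genes are not independent replicates. Paralogs 1 to 6 had 7 of 16 genes higher and 1 lower, paralogs 7 to 10 had 0 of 12 higher and 3 lower, and paralogs 11 to 13 had 1 of 8 higher. Leaving out 1 cluster moved rho between −0.509 and 0.012, so the data leave the hypothesis undecided.

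Another hypothesis was that neighbouring genes change together, in the gene order of assembly GRCm38.p6. There were 145 adjacent pairs of tested genes that passed in the same direction, against 36 to 62 (95% range) in 10000 permuted orders (permutation p = 1e-04, one-sided, the smallest that these can give). Runs of at least 3 such genes included those from Hoxa3 to Hoxa6, from Abca8b to Abca6 and of Gucy1b1, Gucy1a1 and Map9 among the higher genes. Among the lower genes they included those from Irx1 to Irx2, from Irx3 to Irx5 and of the C1q genes. Several runs hold related genes, whose probes may share signal, which the count of 145 does not address. The permuted orders also spread calls evenly over dim genes and the 1088 olfactory receptor genes, of which 3 were higher and 0 lower. Genes that rarely pass may lie in clusters, which would raise the count without neighbours changing together. The test therefore does not decide the hypothesis.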
